A study of Mus musculus with 6 samples.

How the data were processed

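RNA from mouse endometrial epithelial cells was profiled in 6 libraries, 3 without and 3 with galactose treatment, and groups were taken from the treatment given in the labels. Per the labels' protocols, cDNA was primed with a modified oligo(dT), extended by template switching, amplified by long-distance PCR, fragmented enzymatically and sequenced as paired ends on an Illumina NovaSeq instrument. No molecular identifiers and no marking of strand are named, so PCR copies were not separated from original molecules. The protocol selects polyadenylated RNA. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which can be technical. They also give no infection dose, galactose dose or time.

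The authors deposited a table with a count and an FPKM value per gene and library. Per the submitters' processing notes, the tools named were cutadapt 1.9 (adapter trimming), HISAT2 2.2.1 (alignment), StringTie 2.1.6 (assembly and abundance), DESeq2 and edgeR; the roles given here are the tools' usual ones. The genome build, the annotation and the rule by which reads were counted, strand and multiply mapped reads included, are not given in the sources used here. Gene identifiers, symbols and chromosomes are those of the deposited table, and start and end positions were not used in the text because no build is named. Of 12648 gene identifiers 12365 were found in GENCODE M21 (GRCm38), and 263 of those had its exact start and end. The deposited counts were whole numbers in every library. In each gene the ratio of the deposited count to the deposited FPKM was constant over libraries apart from 1 factor per library, with deviations of up to 0.00130 for 99 in 100 values among the 5344 genes above 1000 counts in every library. Every listed gene had an FPKM of at least 1 in at least 1 library, the smallest maximum being 1.00, so genes expressed below that level in all libraries were not analysed here. A gene list can therefore hold fewer measured members than it names.

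Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 12496, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) compared the groups without covariates, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are galactose over no galactose. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. The biological coefficient of variation was 0.333. Positive log2 values thus mean more RNA relative to the library total with galactose, not more RNA per cell.

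Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists with at least 5 tested members, out of 38 lists. Camera with the correlation estimated from the data and fry, both adjusted in the same way, were run beside it. With the estimated correlation and with fry 0 lists passed. Camera asks whether a list differs from the other genes. Fry asks whether its genes move on balance in the same direction. Members were also adjusted over the list alone. The 38 lists were inflammatory cytokines and chemokines, the Toll-like receptor and NF-kB pathway, negative regulators of inflammation, interferon-stimulated genes, inflammasome and pyroptosis, epithelial antimicrobial defence, galactose (Leloir) metabolism, glycolysis, the tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation, NRF2 and antioxidant genes, the unfolded protein response, autophagy and lysosome, apoptosis, ferroptosis, tight and adherens junction, cholesterol biosynthesis, glycan galactosylation with sialylation and galectins, the estrogen and progesterone response, cell cycle and proliferation, extracellular matrix and fibrosis, immediate early and dissociation genes, histone deacetylases and sirtuins, and cytosolic ribosomal proteins. Further lists held markers of epithelium, uterine gland, ciliated epithelium, stromal fibroblasts, smooth muscle and pericytes, mesothelium, endothelium, macrophages and monocytes, neutrophils, T and NK cells, B and plasma cells and erythroid cells, the mitochondrial-encoded transcripts and a sex-linked check. The groups, tests, lists and rule for named genes were fixed before the data were examined.

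The rule named up to 12 genes per direction among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out predicted, RIKEN-named, pseudogene and ribosomal protein symbols. Since 0 genes passed, it named the 6 per direction with the smallest p under the same filters. It also named up to 4 members with the smallest p of each list, and genes of inflammation and galactose metabolism whatever their values, among them Tnf, Il1b, Il6, Cxcl1, Cxcl2, Tlr4, Nfkbia, Galm, Galk1 and Galt. Some genes that the rule names are not reported singly here; they stay in the counts and tests of their lists. Other genes named in the text were chosen after their values were seen.

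Shares of counts, list scores and the dependence of expression on transcript length were compared with exact two-sided permutation tests over the 10 splits of 6 libraries, whose smallest p is 0.1. A list score is the mean over members of log2 CPM minus the gene's mean over the 6 libraries. Transcript length was taken from the ratio of count to FPKM in the deposited table, which followed the transcript lengths of GENCODE M21 with a Spearman rho of 0.942, and GC content from GENCODE M21 transcripts for 97.8% of the genes. Bounds for genes with 0 counts use 3 counts per library. Floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Total counts of 51846742 to 64558145 make counting error small for all but the lowest genes. Libraries within a group differed by far more than that error, so precision rests on the spread among 3 libraries per group.

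The edgeR steps were tested on simulated data with the means, library sizes and fitted dispersion trend of this comparison, the genes varying independently. Of 12496 simulated genes 200 were changed. The test recovered 25 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, 120 in the right direction, and called 10 unchanged genes. Real genes are correlated and differ in dispersion around the trend, so recovery in the real data can be lower. Replicates were compared before averaging, and all pairs within a group differed by far more than sampling noise, with chi-square per degree of freedom from 144 to 523.

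Alternatives were the replicate number as a block, DESeq2 size factors or upper-quartile scaling in the edgeR fit, no filter or a filter at a mean CPM of 5, leaving out each library, leaving out mitochondrial genes, DESeq2 1.42.0 with the Wald test, limma-voom, limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 0.01 for genes with a mean FPKM of at least 1 in a group, and a minimum change of 2-fold. A correction for length and GC content was added after seeing the data. It removed from each library a smooth trend of log2 CPM on both (natural splines with 4 degrees of freedom). Terms of the KEGG and GO annotation in the deposited table with 10 to 300 tested genes, and 8 lists chosen after the data were seen, were tested in the same way with camera and serve the closing observations. Figures were drawn with matplotlib 3.10.9.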

Results

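The transcriptomes of mouse endometrial epithelial cells, the cells that line the uterus, were measured by SMART-seq in 6 libraries. SMART-seq copies polyadenylated RNA from small inputs into cDNA and amplifies it before sequencing. The 3 libraries of the first group came from cells without galactose and the 3 of the second from cells given galactose, a hexose sugar. The series title places the cells after infection with Escherichia coli, and the sample labels name no uninfected group. The single comparison of the design is therefore galactose against no galactose, and it asks how the sugar altered gene expression in these cells. Total counts were 53301151, 54075101 and 55192960 in the libraries without galactose and 64558145, 51846742 and 57447604 in those with it. The count table listed 12648 genes, of which 12496 were tested. The share of counts from mitochondrial messenger RNAs was 1.95% ± 0.275 (SD, n = 3) without galactose and 3.05% ± 0.442 (SD, n = 3) with it. The 20 most abundant genes of each library held 11.9% ± 1.69 and 16.8% ± 4.11 of the counts (SD, n = 3 each). In both measures the libraries of the groups did not overlap, with p = 0.1 in exact two-sided permutation tests, the smallest value that 3 against 3 libraries allow.

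Among the 6 lower genes named by rank, Irgm1, Irgm2, Gbp6 and Oasl2 are interferon-induced. Among the 6 higher ones, Cnfn, Trex2, Tff1 and Ctla2a were nearly absent without galactose. No single gene passed the test over all genes. Irgm1, an interferon-induced GTPase (chromosome 11, ENSMUSG00000046879), was counted at 526 ± 26.3 CPM without galactose and 246 ± 33.0 CPM with it (SD, n = 3 each), a log2 fold change of -1.10 (SE 0.18). Gbp6 (chromosome 5, ENSMUSG00000104713), a guanylate-binding protein, stood at 114 ± 37.0 and 30.8 ± 8.85 CPM, a log2 fold change of -1.88 (SE 0.31). The other genes named by rank on the lower side were Spats2l at -1.31, Irgm2 at -1.23, Oasl2 at -0.76 and Dse, a dermatan sulfate epimerase, at -1.43. On the higher side, Lrrc26, an auxiliary subunit of potassium channels (chromosome 2, ENSMUSG00000026961), stood at 25.2 ± 6.47 and 69.3 ± 18.6 CPM, a log2 fold change of 1.46 (SE 0.27). Cnfn, which encodes the cornified envelope protein cornifelin (chromosome 7, ENSMUSG00000063651), stood at 0.301 ± 0.0673 CPM without galactose. With galactose its 3 libraries gave 32.9, 303 and 5.20 CPM. Trex2, a 3' exonuclease gene, had means of 0.199 ± 0.0850 and 7.35 ± 6.76 CPM, and Ctla2a had 0.556 ± 0.269 and 8.67 ± 7.97 CPM (SD, n = 3 each). Reads of Ctla2a, Gbp6, Irgm1 and Irgm2 can be shared with close paralogs, so their values are uncertain. Tff1, a trefoil peptide of mucosal surfaces, had 0 counts in all 3 libraries without galactose and 12.9 ± 15.1 CPM with it, at least 251-fold above a floor of 3 counts per library, or 84.3-fold without galactose replicate 2. Without that library the log2 fold changes of Cnfn, Trex2 and Ctla2a were 5.98, 4.11 and 2.92. Tnfsf13os had a log2 fold change of 3.09, but it is an antisense gene and no use of strand in counting is stated, so its reads cannot be told from those of the opposite strand.

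These 12 genes were the top 6 per direction by p, each with groups that did not overlap, and none passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.407 for each). The test called 0 genes higher and 0 lower. At an unadjusted p under 0.05 it had 676 higher and 758 lower, 1434 together, where chance gives 624.8. The groups did not overlap for 18.6% of the tested genes, against 10% by chance. Both chance values are averages, and such counts vary widely because genes are correlated. Other divisions of the 6 libraries into 3 and 3 gave 127 to 2682 genes at an unadjusted p under 0.05. DESeq2's Wald test called 74 genes higher and 74 lower, among them all 12 genes above, and limma-voom called 0 higher and 1 lower, Gm42878. Of the 74 lower genes in DESeq2, 12 belonged to the list of interferon-stimulated genes described next, and 0 of the higher ones did. The 1434 genes became 808 without no-galactose replicate 2, 2779 without no-galactose replicate 3 and 553 without galactose replicate 2.

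**Figure D1:**
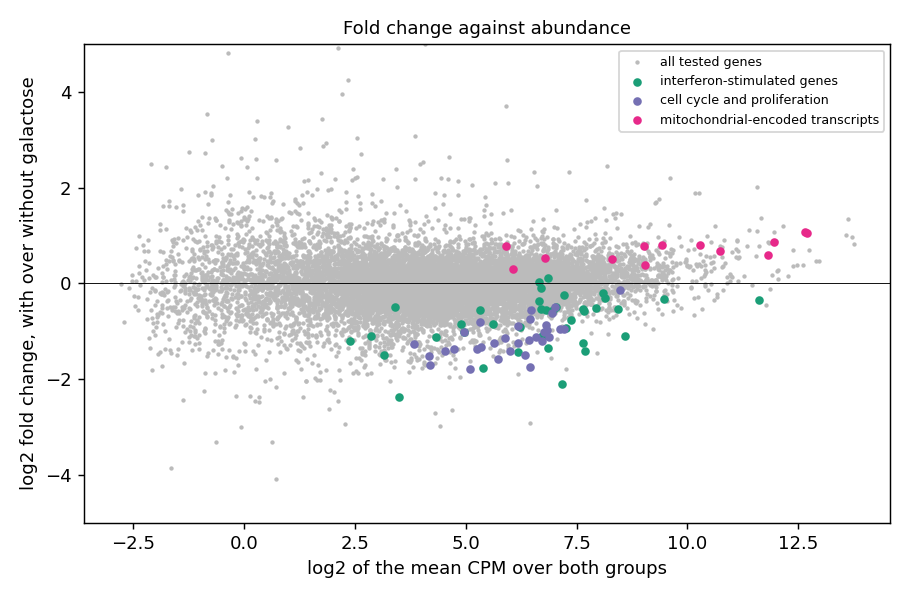
Each point is a tested gene, with the log2 of its mean CPM over both groups on the x axis and its log2 fold change with over without galactose on the y axis. Members of 3 lists are coloured: 36 of 38 interferon-stimulated genes and 32 of 32 cell cycle genes lie below 0, and 13 of 13 mitochondrial-encoded transcripts lie above it; 8 genes lie beyond the y axis.

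Interferon-stimulated genes were lower with galactose as a group. Of 38 measured members, 36 had lower values and 2 higher, with a median log2 fold change of -0.66. Gbp7, another guanylate-binding protein gene, had a log2 fold change of -1.76 (SE 0.41), with 64.5 ± 33.9 and 19.0 ± 6.22 CPM (SD, n = 3 each), uncertain because its reads can be shared with paralogs. Oasl2, of the oligoadenylate synthetase-like family, stood at 208 ± 10.7 and 123 ± 2.83 CPM. In edgeR's test 20 members had an unadjusted p under 0.05, all of them lower. Adjusted over the list alone 17 passed, and 0 passed over all genes. The libraries of both groups did not overlap for 18 members. The list was lower in limma's camera test with a preset correlation (adjusted p = 3.04e-13). It did not pass with an estimated correlation (adjusted p = 0.680 and unadjusted p = 0.0389 with an estimated correlation), nor in fry (p = 0.00816, adjusted p = 0.212). Its score, the mean log2 CPM of the members relative to each gene's mean, was 0.46, 0.03 and 0.67 without galactose and -0.32, -0.30 and -0.54 with it, with an exact permutation p = 0.1. The camera call held without each library in turn. The mitochondrial share and the share of the 20 most abundant genes separated the libraries in the same way as this list.

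**Figure D2:**
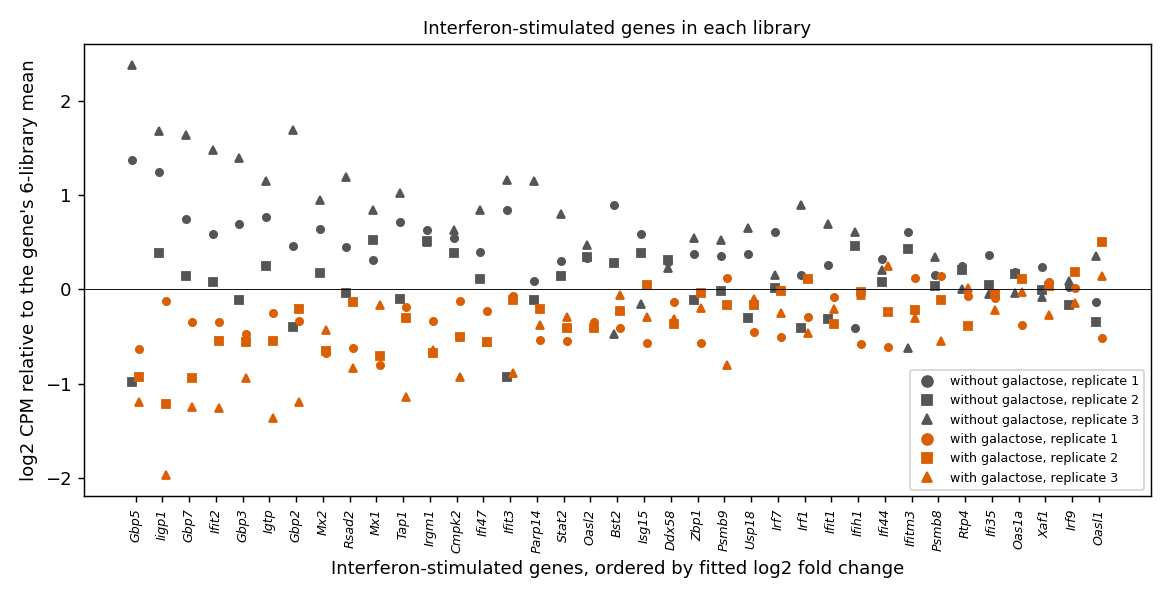
Each point is the log2 CPM of an interferon-stimulated gene in 1 library, relative to that gene's mean over the 6 libraries, with 37 of the measured genes ordered along the x axis by fitted log2 fold change. Grey marks libraries without galactose and orange those with it, and marker shapes give the replicate; the libraries of both groups do not overlap for 17 of the genes shown.

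Cell cycle genes were also lower on average with galactose, with more spread between libraries and overlapping scores. All 32 measured members had lower values and the median log2 fold change was -1.16, from -1.74 to -0.78 when each library was left out. Mki67, a nuclear antigen of cycling cells, had a log2 fold change of -1.78 (SE 0.53), with 53.3 ± 20.8 and 15.5 ± 10.4 CPM. Mcm4, a subunit of the replicative helicase, had -1.58 (SE 0.41), Top2a, a DNA topoisomerase, -1.74 (SE 0.63) and Ccne1, a G1/S cyclin, -1.41 (SE 0.47). When each library was left out, Mki67 ran from -2.41 to -1.38 and Top2a from -2.44 to -1.24. Unadjusted p was under 0.05 for 14 members in edgeR's test, and adjusted over the list alone 0 passed. The list was lower in camera (adjusted p = 1.39e-10) and not with an estimated correlation (adjusted p = 0.680 with an estimated correlation), the correlation between members being 0.848. The list scores overlapped, since no-galactose replicate 3 had -0.18 and galactose replicate 1 had 0.24, with an exact permutation p = 0.2. They separated no-galactose replicates 1 and 2 and galactose replicate 1 (0.76, 1.22 and 0.24) from the rest. No-galactose replicate 3 and galactose replicates 2 and 3 had -0.18, -1.46 and -0.58. That division of the libraries gave 2682 genes at an unadjusted p under 0.05 in edgeR's test, against 1434 for the real groups. The camera call held without each library in turn.

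Inflammatory and antimicrobial genes leaned higher with galactose, with list scores that overlapped between groups. Of 29 cytokines and chemokines 19 were higher and 10 lower, with a median log2 fold change of 0.40, which ran from 0.02 without no-galactose replicate 2 to 1.42 without no-galactose replicate 3. The smallest p was that of Cxcl3, a neutrophil chemoattractant, at 2.19 (SE 0.72), and at 1.45 without galactose replicate 2. Among the genes named in advance, log2 fold changes were 0.73 (SE 0.72) for Tnf, 0.10 (SE 0.77) for Il1b, 0.93 (SE 0.76) for Cxcl1, 0.52 (SE 0.86) for Cxcl2, 0.76 (SE 0.40) for Nfkbia, the inhibitor of NF-kB, and -0.40 (SE 0.44) for Tlr4, the receptor of bacterial lipopolysaccharide. Il6 was not among the tested genes. Negative regulators of inflammation had 14 of 20 members higher (median 0.40, from 0.14 to 0.78 when each library was left out) and epithelial antimicrobial defence 17 of 19 (median 0.46, from 0.20 to 0.74), the latter with Lcn2, a siderophore-binding protein, at 9003 ± 1826 and 17633 ± 7183 CPM, and S100a8 and S100a9, subunits of calprotectin, at log2 fold changes of 2.22 (SE 0.72) and 2.06 (SE 0.76). The groups did not overlap for Cxcl3 and Lcn2. They overlapped for both S100a8 and S100a9, and without galactose replicate 2 their log2 fold changes were 0.92 and 0.77. All 3 lists passed camera (adjusted p = 0.0104, 0.0168 and 0.00346), and none did with an estimated correlation (adjusted p = 0.680 with an estimated correlation for each). The scores had exact permutation p = 0.5, 0.5 and 0.4. Like the cell cycle scores, they separated no-galactose replicates 1 and 2 and galactose replicate 1 from the rest, narrowly for the third list. Without no-galactose replicate 2 the adjusted camera p of the 3 lists was 0.741, 0.829 and 0.146, and without galactose replicate 2 it was 0.112, 0.162 and 0.0791. Without no-galactose replicate 1 it was 0.0550 for the first list and 0.0550 for the second. Without no-galactose replicate 3 it was 2.14e-06, 2.68e-05 and 0.00920. In that setting the log2 fold changes of Cxcl1 and Cxcl2 were 2.27 and 2.34, that of Il1b was 1.66 and that of Tnf 1.65. Without no-galactose replicate 2 they were 0.45 for Cxcl1, 0.02 for Cxcl2 and -0.36 for Il1b. Without galactose replicate 2 that of Tnf was -0.14. The Toll-like receptor and NF-kB pathway list did not pass (29 genes, median -0.04, mean -0.01, camera direction up, adjusted p = 0.841), nor did the inflammasome and pyroptosis list (11 genes, median -0.08, camera direction up, adjusted p = 0.791).

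Transcripts of mitochondrial energy production were higher with galactose. All 13 mitochondrial-encoded messenger RNAs had higher values, with a median log2 fold change of 0.78. mt-Co3, of cytochrome c oxidase, had 1.07 (SE 0.30), mt-Atp6 had 0.87 (SE 0.25) and mt-Atp8 had 0.79 (SE 0.19), both of ATP synthase. Adjusted over the list alone 10 passed, and 0 over all genes. The list passed camera (adjusted p = 1.22e-08; adjusted p = 0.680 with an estimated correlation), and its scores did not overlap, with an exact permutation p = 0.1. Of 49 nuclear-encoded oxidative phosphorylation genes 42 were higher, with a median of 0.28 (from 0.17 to 0.35 when each library was left out), and the groups separated with galactose higher for 31 of them. Ndufa13 had a log2 fold change of 0.67 (SE 0.19), Ndufa4 0.56 (SE 0.19) and Cox4i1 0.54 (SE 0.19). That list passed camera (adjusted p = 6.74e-07; adjusted p = 0.680 with an estimated correlation), with an exact permutation p = 0.1 for its scores, and 0 of its genes passed adjusted over the list alone. Both calls held without each library in turn. Of 40 cytosolic ribosomal protein genes 36 were higher (median 0.31, from 0.11 to 0.43 when each library was left out), with Rps14 at 0.65 and Rps27 at 0.58. This list passed camera (adjusted p = 3.39e-06; adjusted p = 0.680 with an estimated correlation), but without no-galactose replicate 3 its adjusted p was 0.161. The share of counts in ribosomal protein genes was 1.62% ± 0.402 and 1.69% ± 0.0769 (SD, n = 3 each), with an exact permutation p = 1. That share is of the total count, whereas fold changes use TMM-scaled library sizes. Short transcripts leaned higher with galactose. The Spearman rho between length and log2 CPM relative to each gene's mean was -0.06, 0.07 and 0.37 in the libraries without galactose. It was -0.20, -0.26 and -0.10 in those with it (exact permutation p = 0.1). No-galactose replicate 3 stood furthest from the rest. The median log2 fold change was 0.16 in the fifth of genes with the shortest transcripts and -0.20 in the fifth with the longest, and across genes, which are not independent replicates, fold change and length had a Spearman rho of -0.295.

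Galactose-processing genes did not pass as a list. The 12 genes of the Leloir pathway and its neighbours had a median log2 fold change of 0.16 and did not pass camera (adjusted p = 0.286). Galm, the galactose mutarotase, had -0.09 (SE 0.44), Galk1, galactokinase, 0.28 (SE 0.17) and Galt, the uridylyltransferase, -0.15 (SE 0.19), with adjusted p of 0.943, 0.504 and 0.761 in edgeR's test. The groups did not overlap for Galk1 and for Glb1, a beta-galactosidase, which had 0.28 (SE 0.17). Galm moved from -0.77 without galactose replicate 1 to 0.18 without galactose replicate 2. Glycolysis genes had 17 of 20 members higher (median 0.29, from 0.16 to 0.58 when each library was left out), with Aldoa at 0.68 and Slc2a1, a glucose transporter, at 0.74, while Hk1, a hexokinase, stood at -0.47. The glycolysis list passed camera (adjusted p = 0.0267; adjusted p = 0.680 with an estimated correlation), and not without no-galactose replicate 1 (0.257) or 2 (0.146), or without galactose replicate 2 (0.162) or 3 (0.212). The tricarboxylic acid cycle list did not pass (20 genes, median -0.09, adjusted p = 0.245). Cholesterol biosynthesis had 18 of 23 members lower (median -0.28, from -0.71 to -0.05 when each library was left out), with Idi1 at -0.98 and Hmgcs1 at -0.79, or -1.96 and -1.48 without galactose replicate 3. It passed camera (adjusted p = 0.0146; adjusted p = 0.680 with an estimated correlation), and not without galactose replicate 1 (0.662), galactose replicate 2 (0.0607) or no-galactose replicate 2 (0.180).

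Immediate early genes and epithelial and mesothelial markers were higher on average with galactose. Of 23 immediate early and dissociation genes, which respond quickly to stimulation and tissue handling, 22 were higher, with a median log2 fold change of 0.74, from 0.34 to 1.29 when each library was left out. Jund had 0.86 (SE 0.27), Fos 1.05 (SE 0.46) and the near-identical heat shock genes Hspa1a and Hspa1b 0.73 and 0.65, the latter pair being uncertain because their reads can be shared. Epithelium markers had 17 of 20 members higher (median 0.44, from 0.28 to 0.57 when each library was left out), with Krt19 at 2554 ± 165 and 5420 ± 2071 CPM and Krt8 at 2315 ± 146 and 3995 ± 1404 CPM (SD, n = 3 each), both keratins of simple epithelia, while Grhl2 stood at -0.47. Mesothelium markers had 6 of 6 higher (median 1.79), all at low levels, such as Upk3b at 2.33 ± 0.604 and 7.56 ± 4.63 CPM. Their median was 1.04 without galactose replicate 2. Krt14, a member, reached an FPKM of 1 only with galactose, so the choice of listed genes favours a median above 0. Those 3 lists passed camera (adjusted p = 3.39e-06, 0.00331 and 0.000787; adjusted p = 0.680 with an estimated correlation for each), and the calls held without each library in turn, with an adjusted p = 0.0411 for epithelium markers without galactose replicate 2. The scores separated the groups only for mesothelium markers among these 3 lists (exact permutation p = 0.3, 0.2 and 0.1). Those of immediate early genes were -0.55, -1.11 and 0.43 without galactose and -0.05, 1.02 and 0.25 with it. Epithelium markers had -0.23, -0.32 and -0.01 without galactose and -0.14, 0.52 and 0.17 with it. Both, like the cell cycle scores, separated no-galactose replicates 1 and 2 and galactose replicate 1 from the rest. The estrogen and progesterone response list had 14 of 18 higher (median 0.52, from 0.36 to 0.75 when each library was left out), led by Sprr2f at 8116 ± 2182 and 16467 ± 5713 CPM, uncertain because its reads can be shared with paralogs, and by Padi2, a peptidylarginine deiminase, at a log2 fold change of 1.23. It passed camera (adjusted p = 0.0287; adjusted p = 0.680 with an estimated correlation), and not without no-galactose replicate 1 (0.0550), no-galactose replicate 2 (0.0531) or galactose replicate 2 (0.116).

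Markers of other cell types were few in the table and mostly low. Of 17 stromal fibroblast markers 3 were listed, too few for camera: Dcn, a matrix proteoglycan, had 6.79 ± 3.43 and 42.8 ± 38.7 CPM, Lum 0.570 ± 0.591 and 6.21 ± 6.31 CPM, and Fbln1 196 ± 33.4 and 224 ± 46.1 CPM (SD, n = 3 each). Adjusted over the list alone 2 of these 3 passed. Without galactose replicate 2 the log2 fold change of Dcn was 1.63 and that of Lum 2.19, against 2.65 and 3.44 with all libraries. Macrophage and monocyte markers had 8 of 9 higher (median 0.44, from 0.08 to 0.76 when each library was left out), with Cd68 at 1.34. They passed camera (adjusted p = 0.0264; adjusted p = 0.680 with an estimated correlation), and not without no-galactose replicate 1 (0.0577) or 2 (0.303), or without galactose replicate 2 (0.162) or 3 (0.0683). The call also ended with a filter at a mean CPM of 5 (0.0654). Neutrophil markers did not pass (6 genes, median 0.81, from 0.28 to 1.39 when each library was left out, adjusted p = 0.163), except without galactose replicate 1 (0.00267), nor did uterine gland markers (7 genes, median -0.38, adjusted p = 0.615). Lists with fewer than 5 measured members were not tested with camera. Their median log2 fold changes were 0.34 for 3 endothelium markers, -0.31 for 2 smooth muscle and pericyte markers and -0.25 for 3 T and NK cell markers. For the lists with 1 tested member they were 0.45 for the ciliated epithelium marker Rsph1, -0.17 for the B cell marker Cd79b and 1.11 for the erythroid marker Hba-a1, which had -0.05 without galactose replicate 2. Of the sex-linked genes only Xist was tested, at 141 ± 19.2 and 153 ± 13.7 CPM (SD, n = 3 each).

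Among the remaining lists only that of autophagy and lysosome genes passed camera, with 21 of 29 members higher, a median log2 fold change of 0.25 (from 0.10 to 0.43 when each library was left out) and Gabarap, of the autophagosome membrane, at 0.74 (adjusted p = 0.00618; adjusted p = 0.680 with an estimated correlation). It did not pass without no-galactose replicate 2 (0.153) or galactose replicate 2 (0.0607). Extracellular matrix and fibrosis genes missed the threshold (14 genes, median 0.33, from 0.16 to 0.63 when each library was left out, adjusted p = 0.0576) and passed without no-galactose replicate 3 (0.0151) or galactose replicate 1 (0.0221). Sparc, a matrix glycoprotein and the 1 member that passed adjusted over the list alone, had 3.44 ± 1.37 and 18.0 ± 12.4 CPM, a log2 fold change of 2.39, or 1.68 without galactose replicate 2. Apoptosis genes did not pass (27 genes, median 0.13, adjusted p = 0.101), except without no-galactose replicate 3 (0.00920); Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 1.53 (SE 0.39). NRF2 and antioxidant genes did not pass (30 genes, median 0.10, adjusted p = 0.164), with the glutathione peroxidases Gpx1 at 0.88 and Gpx2 at -1.19. Camera also gave adjusted p = 0.610 for the unfolded protein response (28 genes, median -0.03), 0.467 for ferroptosis (20 genes, median 0.10) and 0.615 for tight and adherens junction genes (28 genes, median -0.03, camera direction up). It gave 0.868 for glycan galactosylation, sialylation and galectins (24 genes, median -0.08, camera direction up) and 0.911 for histone deacetylases and sirtuins (17 genes, median -0.01, camera direction up). In the glycan list Lgals3, which encodes the galactoside-binding lectin galectin-3, stood at 338 ± 138 and 797 ± 306 CPM (SD, n = 3 each).

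**Figure D3:**
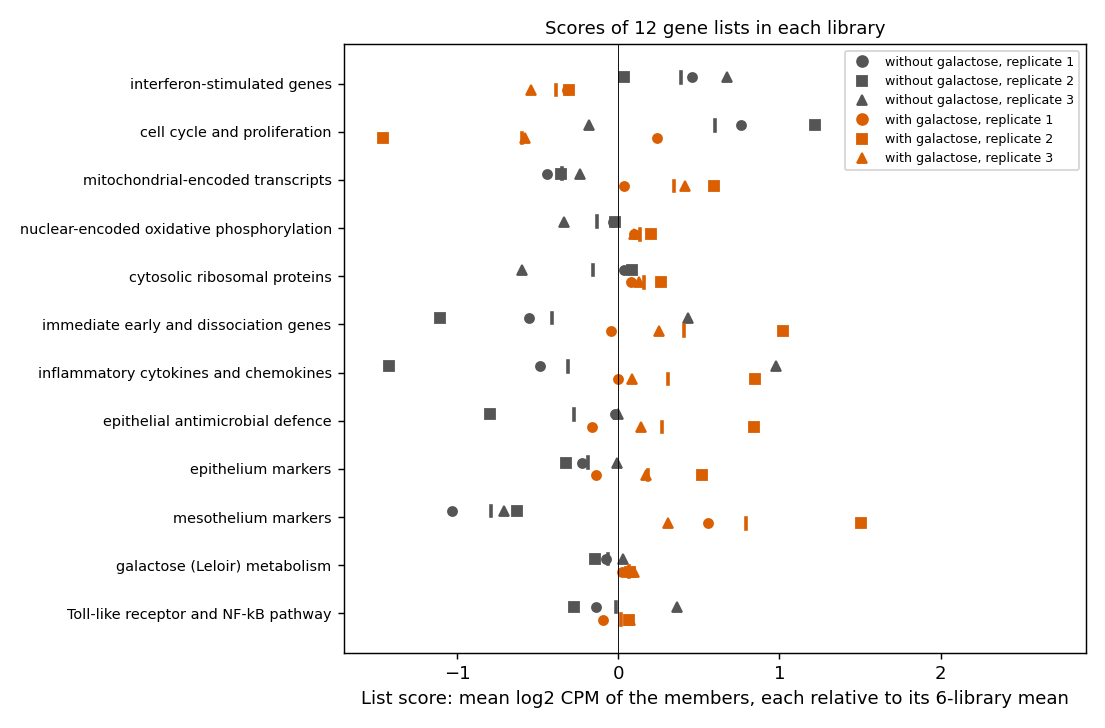
Each point is the score of a gene list in 1 library, the mean log2 CPM of its members relative to each gene's mean over the 6 libraries, on the x axis, for 12 lists on the y axis. Vertical bars are group means (n = 3), grey without and orange with galactose; the interferon-stimulated genes run from 0.03 to 0.67 without galactose and from -0.54 to -0.30 with it.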

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

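The length and GC correction was chosen after seeing the data, and all other settings were planned. In edgeR's quasi-likelihood test 0 genes passed in either direction with the replicate block, both other scalings, both other filters, without mitochondrial genes, with a 2-fold minimum and after the length and GC correction, and 0 passed in limma on FPKM values. DESeq2's Wald test called 74 genes higher and 74 lower, and limma-voom called 1 lower, Gm42878, which had 0 counts in all galactose libraries. Leaving out each library gave 0 to 1 genes higher and 0 lower; the genes were Septin2 (ENSMUSG00000116048) without no-galactose replicate 1 and Tnfsf13os without galactose replicate 1. The cause of these differences was not tested.

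Lists passing camera numbered 13 higher and 3 lower. With an estimated correlation 0 passed higher and 0 lower, and with fry 0 passed higher and 0 lower; both settings allow for correlation among the members. Leaving out each library gave 6 to 15 higher, with 8 without no-galactose replicate 1, 6 without no-galactose replicate 2 and 6 without galactose replicate 2, and 2 to 3 lower; the cause was not tested. Of the 16 lists, 7 passed without each library in turn and 15 passed after the length and GC correction, the exception being macrophage and monocyte markers (adjusted p = 0.0748). Extracellular matrix and fibrosis genes passed with the replicate block (adjusted p = 0.0139) and after the length and GC correction (0.0491). All 16 kept their camera direction in every setting that tested them; mesothelium markers were too few for a test at a mean CPM of 5.

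The labels do not say whether the replicate numbers pair the samples, and correlations over 3 libraries per group cannot settle it. Deviations from the group mean correlated at 0.306, -0.338 and 0.0773 between libraries of the same number, and not every library correlated best with its own number, since no-galactose replicate 3 had 0.353 with galactose replicate 2. With the replicate block 0 genes passed higher and 0 lower, 1032 had an unadjusted p under 0.05, and 14 lists were higher and 3 lower.

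Of the 147 named genes 133 kept their sign in every setting and 14 did not, none of them past the threshold in any setting; these include Tnf, Il1b, Galm and Galk1. In limma on FPKM the median log2 fold change of all genes was -0.15, -0.19 and -0.20 with pseudocounts of 1, 0.1 and 0.01, against -0.03 in edgeR, so directions there are relative to that shift. Genes changed 2-fold were recovered in 25 of 100 simulated cases, so the call of 0 genes does not exclude changes of that size. Larger changes are not excluded either. Trex2 at a log2 fold change of 5.19 and Gbp6 at -1.88 had an adjusted p = 0.407 in edgeR's test.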

Other observations

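The gene lists and terms on further interferon-stimulated genes, antigen presentation, Sprr2 genes and annotation were chosen after the results of the fixed lists were seen. A separate list of 64 further interferon-stimulated genes, sharing no member with the list above, had 59 members lower with galactose. Gbp4 stood at 182 ± 88.9 and 61.6 ± 14.1 CPM, Tgtp1 at 236 ± 84.7 and 68.9 ± 35.5 CPM, and Gbp10 at 44.2 ± 32.3 and 7.08 ± 3.90 CPM (SD, n = 3 each), all members of GTPase families whose reads can be shared between paralogs. Camera gave this list an adjusted p = 1.28e-14 over 8 lists (adjusted p = 0.0874 with an estimated correlation), and fry an adjusted p = 0.0216. Of 19 genes of class I antigen presentation 11 were lower and 8 higher (median log2 fold change -0.46, camera adjusted p = 0.0177; adjusted p = 0.444 with an estimated correlation). Its scores overlapped between groups, with an exact permutation p = 0.3. Nlrc5, the activator of class I genes, stood at -1.56 and B2m at 0.18. Of 8 class II genes 8 were lower (median -0.75, adjusted p = 0.0287; adjusted p = 0.444 with an estimated correlation), with scores that also overlapped. The GO term for the cellular response to interferon-beta was lower too (43 genes, median -0.77, adjusted p = 3.54e-06; adjusted p = 0.998 with an estimated correlation).

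The Sprr2 genes, which encode small proline-rich proteins of the cornified envelope, were higher in 9 of 10 members with a median log2 fold change of 1.89. Sprr2a3 stood at 489 ± 196 and 1802 ± 615 CPM and Sprr2i at 8.43 ± 7.03 and 111 ± 50.2 CPM (SD, n = 3 each), while Sprr2g had -0.14; the members are near-identical and their single values uncertain. Camera gave the family an adjusted p = 1.42e-06 (adjusted p = 0.176 with an estimated correlation), and 7 members passed edgeR's test adjusted over the list alone. The GO term cornified envelope, which holds such genes, was higher as well (27 genes, median 1.02, adjusted p = 3.66e-06; adjusted p = 0.998 with an estimated correlation). Among lower terms, DNA replication (101 genes, median -0.63) and chromosome segregation (79 genes, median -0.54) had adjusted p = 4.72e-08 and 2.94e-07, with adjusted p = 0.998 with an estimated correlation for both. Of 306 KEGG terms 15 were higher and 13 lower and of 2843 GO terms 67 were higher and 180 lower, and with an estimated correlation 0 of either passed.

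In the tests that follow, those on immune markers, on the single library, on squamous genes, on the ratio of Cnfn to Dcn and on the classes of interferon genes were chosen after the result was seen, and so was the length and GC correction as a setting. The single-library test was first run on the ribosomal protein and oxidative phosphorylation lists together, came out mixed, and was then divided by list. The immune test was first run on all immune markers, with a median of 0.44, and was then divided by cell type. The ratio of Cnfn to Dcn was first taken without subtraction, at 9.57-fold, the classes of interferon genes were first judged by the permutation alone, and the name of the last pattern was reworded, as Dcn was not near absent. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Of these, 10 gave as many genes past the threshold as the real one, which had 0, as did the highest other. With 0 in the real split every split gives at least as many, so this count decides nothing. At an unadjusted p under 0.05 the real split had 1434 genes, and the highest other had 2682, which sets no-galactose replicates 1 and 2 with galactose replicate 1 against the rest, so 2 of 10 splits gave as many. That split was picked as the largest. It also divides the libraries along their first principal component, the axis of largest variation in log2 CPM, with 46.35% of the variance. No-galactose replicates 1 and 2 and galactose replicate 1 stood there at -38.2, -57.9 and -7.10. No-galactose replicate 3 and galactose replicates 2 and 3 stood at 15.9, 60.5 and 26.7. That axis thus does not separate the groups. Scores of the glycolysis list and of the macrophage and monocyte markers also divided that way. What causes this division was not tested. For lists the real split had 16, and 4 of 10 gave as many, the highest other 19. For the interferon-stimulated list the real split had a -log10 camera p of 13.99 and the highest other 11.98, so 1 of 10, the real one, was as large.

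A lower interferon response with galactose is a candidate explanation for the lower interferon-stimulated genes. The separate list of 64 genes, whose prediction was written before its values were seen, had a median log2 fold change of -0.60 with library scores that separated the groups. It extends the pattern to more genes of the same kind in the same libraries. It would also be lower under the explanations left open below, so it does not single out this one. The tables argue against a trend of length or GC content as the cause, since after its correction the median of the fixed list was -0.69. Markers of macrophages and neutrophils gave no sign of fewer such cells, as 11 of them had a median of 0.64 and the lowest stood at -0.11. They do not exclude it, because some were near the floor, such as Fcgr3 at 0.981 CPM without galactose. The scores of both marker lists also overlapped between groups (exact permutation p = 0.3 and 0.5). Fewer T and NK cells stay open, as only 3 of their markers were tested, with a median of -0.25 and Gzma at -1.52. Within the fixed list the 13 genes of the interferon gamma class had a median of -1.24 and 21 antiviral genes -0.55 (permutation p = 0.00128, 100000 resamples), but that p treats correlated genes as independent and the gamma class did not pass camera with an estimated correlation (adjusted p = 0.176), so the type of interferon stays open. Differences in infection, cell number or RNA quality between the groups stay open, because no test here parts them from galactose. The design also has no uninfected or galactose-only libraries.

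The higher ribosomal protein and oxidative phosphorylation lists were weighed against the general lean towards short transcripts. After the length and GC correction the ribosomal protein list had a median log2 fold change of 0.18 against 0.31 before. The oxidative phosphorylation list had 0.20 against 0.28, and both passed camera (adjusted p = 0.00230 and 0.000855). The correction used 1 length per gene, such as 3656 bases for Rps19, which need not be the length of the transcripts present. It therefore cannot exclude a length trend as their whole cause. Without no-galactose replicate 3 the ribosomal protein list had a median of 0.11 and did not pass, so that library may account for it. The oxidative phosphorylation list had 0.17 without that library and passed (adjusted p = 0.00489), which argues against that library as its whole cause. A response of the cells to galactose and a difference in RNA quality stay open for the oxidative phosphorylation genes, and no test here parts them.

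Cnfn, Tff1, Trex2 and Lum were near absent and Dcn low, at 6.79 CPM, without galactose, and all 5 were uneven with it, which could come from other cells in some libraries. A common source of all 5 genes stays open: with the mean level without galactose taken off, the ratio of Cnfn to Dcn differed 5.76-fold among the galactose libraries, and with the highest level taken off 3.64-fold. For squamous epithelium, 8 listed genes under 10 CPM without galactose had a median log2 fold change of 1.49, but 3 of them reached an FPKM of 1 only with galactose, so their choice favours a median above 0 and decides nothing. The whole squamous list, with 13 of 29 genes tested, had a median of 0.88 and passed camera (adjusted p = 0.000900) but not with an estimated correlation (adjusted p = 0.176), so squamous cells and cornification within the endometrial cells both stay open. For stromal cells, 3 further genes gave a median of 0.58, between the bounds of 0.2 and 1 set before, and the whole list, with 8 genes tested and 5 of them higher, had a median of 0.29 (camera adjusted p = 0.192), so stromal cells and a change within the epithelium cannot be told apart for Dcn and Lum.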
